A study of Homo sapiens with 9 samples.

How the data were processed

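RNA from cultured human umbilical cord mesenchymal stromal cells was measured on 9 Illumina expression arrays. Per the labels, 3 arrays came from untreated cells, 3 from cells exposed to Omnipaque (iohexol) and 3 from cells exposed to Isovue (iopamidol), each dye at 1 part to 4 parts of medium for 24 h. Per the labels, RNA was amplified with a nano-scale labelling kit, carried biotin and was hybridised with the Illumina Direct Hybridization Assay. The labels name GenomeStudio and Partek, and their versions and roles are not given in the sources used here. The array type, the array chip of each sample and the iodine concentration of each dye are not given in the sources used here.

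Both deposited tables were used. The deposited probe table holds, per the file headers, the average signal of each of 47322 probes as an intensity on the linear scale. Its 9 columns of detection p-values were left unused, as 1 measure was kept where column labels match a group and not a sample. This deposited table is called non-normalized, but the quartiles of its 9 signal columns lay within 0.338 units of each other, as after quantile normalization by the authors, and no background had been subtracted. The probes carry no gene names in the deposited files, and the probe columns were matched to groups, not to single samples. The deposited gene table holds 34686 rows, 1 per gene symbol, in log2 of the same quantile-normalized signals, as its values show. For 70.36% of its rows, the values equalled log2 of a single probe's signal to 3 decimals on all 9 arrays.

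The design fixed before the data were examined called for background correction of named probes by means of their detection p-values and the brightest probe per gene. That was not run as written, since the files give the probes no names and label their columns by group only. The equal values for 70.36% of rows tie the columns to samples and could name those probes, but this link was not used. A first full analysis used the detection p-values for the background and the filter, tested fewer genes and is not reported here. This processing, with the detection limit below, replaced it and was chosen after the data and those results had been seen. The gene table was returned to the linear scale and its background corrected by the normexp model, fitted to each array by maximum likelihood (background mean 99.3 to 99.48, standard deviation 0.985 to 1.25). An offset of 50 was added, the values were returned to log2 and the arrays were quantile-normalized again. A gene counted as detected on an array above a deposited signal of 121. That limit is the upper 1% of a normal background around the mode of the probe signals (110.5), with a standard deviation of 4.483 from the signals below the mode. Genes detected on at least 3 arrays were tested. This left out 15322 rows, and 84 rows of sex-linked genes were left out for privacy, so that 19280 genes were tested. Of these, 13599 carried a current symbol in the RefSeq gene table, and 5817 carried placeholder names, which were tested but not named. Genes are called by the symbols in the files, with the current symbol beside older ones.

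Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated tests) to all 9 arrays with group as the only term. The residual degrees of freedom were 6 and the prior added 2.764. The contrasts were Omnipaque minus control, Isovue minus control and Isovue minus Omnipaque. P-values were adjusted by the Benjamini-Hochberg method over all tested genes within each contrast, with a threshold of 0.05. Errors are standard errors of the fitted difference or standard deviations (SD) over 3 arrays, and intervals are 95% intervals from the fit. The number of arrays limits the precision. Where no array of 1 group detected a gene, the fold is given as at least the ratio of the other group's mean to the detection limit.

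The 27 gene lists, the rule for named genes and the tests were chosen before the data were examined, except where stated. The lists were hypertonic response, unfolded protein response, ATF4 and integrated stress response, p53 targets, apoptosis machinery, cell cycle and proliferation, and NRF2 and antioxidant genes. Further lists were heat shock proteins, NF-kB and inflammatory secretion, interferon response, extracellular matrix, matrix proteases and inhibitors, and mesenchymal stromal surface markers. The remaining lists of cell functions were osteogenic, adipogenic and chondrogenic genes, SRF and YAP targets, cholesterol synthesis, hypoxia and glycolysis, lysosome and autophagy, oxidative phosphorylation, ribosomal proteins, metallothioneins and zinc transport, immediate early genes and thyroid hormone handling. Markers of endothelial, epithelial and blood cells and of smooth muscle and pericytes covered other cell types a cord culture could hold. All 552 members matched a row of the gene table, directly or by an older symbol, and 495 were tested. The 26 lists with at least 5 tested members were tested against all other genes with limma's camera (preset correlation 0.01), adjusted over all lists and contrasts. Camera with a correlation estimated per list (statmod 1.5.0) and fry were run beside it. Members past the threshold were counted over all genes and adjusted over the list alone.

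For each dye against control, the named genes were the 8 largest rises and the 8 largest falls among genes past the threshold. Their 3 treated arrays all lay on one side of the 3 control arrays, and all 3 arrays of the higher group detected them. Up to 3 changed members of each list were added, or the member with the largest difference where none passed. The same rule for Isovue against Omnipaque took all 12 genes past the threshold. Any other gene named was chosen after its values were seen.

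The alternatives covered median scaling, cyclic loess, 2 other background treatments, 3 detection filters, single probes, trend and robust moderation, array weights, a 2-fold threshold, a test against a fold of 1.2, the compared groups alone, a replicate block and each array left out. The background from the mode of the signals with an offset of 16, the looser limit at the upper 5% of that background, and leaving out Omnipaque 3 and Isovue 3 together were added after the data were seen. The replicate numbers were not treated as pairs, since the labels do not say that they are. Pairing is not excluded, as 6 of 9 arrays correlated best with an array of their own number in the group-centred values, and the replicate block is given as an alternative. That count is weak, since Omnipaque 1 correlated nearly as well with Isovue 2 (0.359) as with Isovue 1 (0.363). The steps were tested on simulated data, with 200 of 19280 genes changed and the spread of each group kept. The simulated values were normal, with the same spread on all 3 arrays of a group, and so do not reproduce 1 outlying array.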

Results

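The data were 9 arrays of cultured human umbilical cord mesenchymal stromal cells, 3 each for untreated cells, cells exposed to Omnipaque and cells exposed to Isovue. Both are nonionic iodinated X-ray contrast agents, and the series asks about their toxicity to these cells. Between 17773 and 17899 genes were detected per array, from 51.36% to 51.73% of the genes in the table without those left out for privacy. The median deposited log2 signal was 6.93 on each array. The deposited signals were already quantile-normalized, so these counts and medians are nearly equal by construction and do not measure the quality of an array. Isovue replicate 3 stood apart, with a median correlation across genes of 0.937 with the other arrays, against 0.987 to 0.993 for each of the other 8. On the first principal component, which held 64.43% of the variance, this array was separated from the rest. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure the spread between these samples. The controls are labelled untreated, and no matching dilution of their medium is given in the sources used here. Changes after either dye can therefore not be told apart from those of diluted medium.

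After 24 h with Omnipaque, genes of cholesterol synthesis rose, and genes of the interferon response and metallothioneins and the chemokine gene IL8 (now CXCL8) fell. HMGCS1, which makes the precursor of mevalonate, rose by a log2 change of 1.74 (SE 0.129, adjusted p = 0.00097), from 10.36 ± 0.0289 to 12.11 ± 0.282 (SD, n = 3 arrays each). ISG20, an interferon-induced exonuclease, fell by 1.48 on the log2 scale (SE 0.0739, adjusted p = 0.000133). Of 19280 genes tested with limma, 145 passed the threshold (0.752%), 82 higher and 63 lower, and 38 of them changed at least 2-fold, 27 upward and 11 downward.

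Of 23 tested genes of cholesterol synthesis, 14 rose after Omnipaque and none fell (20 rose when adjusted over the list alone). The list's median log2 change was 1.26, with a camera adjusted p of 4.589e-36, and adjusted p = 0.0171 with an estimated correlation. ACAT2, which joins acetyl groups at the start of the pathway, rose by a log2 change of 1.74. IDI1 and SQLE, which act midway, rose by 1.39 and 1.39, and DHCR7 and SC5DL (now SC5D), which act near its end, by 1.62 and 1.53. ACSS2, which makes acetyl-CoA and is outside the list, rose by 1.47. The list means were above the control mean on all 3 Omnipaque arrays, at 0.99, 1.01 and 1.30.

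Of 20 tested interferon response genes, 7 fell after Omnipaque and none rose (14 fell when adjusted over the list alone). The median log2 change was -0.72 (camera adjusted p = 1.437e-23, and adjusted p = 0.0114 with an estimated correlation). OAS3 and OAS2, sensors of double-stranded RNA, fell by log2 changes of -1.15 and -1.06, and ISG15, a ubiquitin-like modifier, by -0.91. Outside the list, the interferon-induced genes MX2 and OASL fell by log2 changes of -1.62 and -1.12. SLC15A3, a lysosomal peptide carrier, and HES4, a transcription factor, fell by -1.06 and -1.06. Of 8 tested metallothioneins and zinc transport genes, 3 fell (5 when adjusted over the list alone), namely MT1G (-0.77), MT1F (-0.71) and MT1X (-0.58). Their list had a median of -0.41 (camera adjusted p = 1.589e-08, and adjusted p = 0.0124 with an estimated correlation). Of 24 tested genes of NF-kB and inflammatory secretion, 2 fell. IL8 (now CXCL8), which attracts neutrophils, fell by a log2 change of -1.45 and TNFAIP3, which restrains NF-kB, by -0.88. In the NF-kB list, 1 rose and 8 fell when adjusted over the list alone, with a median of -0.37 (camera adjusted p = 9.448e-07, and adjusted p = 0.0218 with an estimated correlation).

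Among the other rises after Omnipaque, GPNMB, a glycoprotein of lysosomal membranes, rose by a log2 change of 1.42. VWF, a clotting glycoprotein of endothelial cells, rose by 1.33 (SE 0.134, adjusted p = 0.00529). Of 25 lysosome and autophagy genes, NPC1 and NPC2, which move cholesterol out of lysosomes, rose by log2 changes of 1.09 and 0.48 (4 rose when adjusted over the list alone). The lysosome list's median was 0.38 (camera adjusted p = 2.295e-07, and adjusted p = 0.0224 with an estimated correlation). Of 16 hypertonic response genes, S100A4 rose by a log2 change of 1.38 and SLC5A3, a myo-inositol carrier, by 1.09 (3 rose when adjusted over the list alone). The hypertonic list had a median of 0.12 and a camera adjusted p of 0.00158, which became adjusted p = 0.0534 with an estimated correlation. Of 23 NRF2 and antioxidant genes, AKR1C3, an aldo-keto reductase that acts on steroids, rose by a log2 change of 1.32 and ME1, which makes NADPH, by 0.96 (8 rose when adjusted over the list alone). The NRF2 list had a median of 0.20 and a camera adjusted p of 3.885e-05, which became adjusted p = 0.165 with an estimated correlation.

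Of 35 tested genes of cell cycle and proliferation, 34 had negative log2 changes after Omnipaque, with a median of -0.80, but no member passed the threshold over all genes or adjusted over the list alone. The camera adjusted p of the cell cycle list was 5.757e-11, which became adjusted p = 0.4 with an estimated correlation. CDC20, an activator of mitotic exit, differed by a log2 change of -1.33 (SE 0.591, adjusted p = 0.455), and by -0.59 without Omnipaque replicate 3. The list means on the Omnipaque arrays were -0.30, -0.37 and -1.54, lowest on replicate 3. None of the 17 immediate early genes passed the threshold over all genes (2 fell when adjusted over the list alone), with a median of -0.28. The immediate early list's camera adjusted p was 0.000762, which became adjusted p = 0.416 with an estimated correlation, and its list mean was also lowest on replicate 3 (-0.73, against -0.22 and -0.22). FOSB, an AP-1 subunit, differed by -1.15 (adjusted p = 0.164). None of the 31 ribosomal protein genes passed over all genes or adjusted over the list alone, with a median of -0.08. The ribosomal list's camera adjusted p was 0.046, which became adjusted p = 0.416 with an estimated correlation. That call ended without control replicate 1 (0.204), Omnipaque replicate 1 (0.152) or Omnipaque replicate 2 (0.0906).

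Camera made no call after Omnipaque for the remaining 16 tested lists. In the unfolded protein response, SDF2L1, an endoplasmic reticulum chaperone partner, fell by a log2 change of -0.67 as 1 of 19 genes (3 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.124). TIMP2 (0.51), an inhibitor of matrix proteases, rose among 13 matrix proteases and inhibitors (2 higher when adjusted over the list alone; camera adjusted p = 0.565). CD9 (0.69) rose among 14 mesenchymal stromal surface markers (3 higher when adjusted over the list alone; camera adjusted p = 0.0975). VWF was the 1 of 5 endothelial cell markers to rise (1 when adjusted over the list alone; camera adjusted p = 0.324).

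No member passed the threshold after Omnipaque in p53 targets (camera adjusted p = 0.448), apoptosis machinery (0.809), extracellular matrix (0.229), osteogenic, adipogenic and chondrogenic genes (0.765), hypoxia and glycolysis (0.783) or oxidative phosphorylation (0.783), and none did adjusted over the list alone. The members with the largest differences in these lists were PMAIP1 (-0.51), TNFRSF10A (0.39), COL12A1 (0.61), ID2 (0.44) and ALDOC (0.95), as log2 changes. ALDOC lay at 9.47, 9.55 and 10.65 on Omnipaque replicates 1, 2 and 3, and at 8.905 to 8.967 on the control arrays. NDUFS1, the largest in oxidative phosphorylation, was detected on 2 control arrays and no Omnipaque array and differed at least 1.06-fold (adjusted p = 0.476). No member passed over all genes in ATF4 and integrated stress response (camera adjusted p = 0.328; 2 higher when adjusted over the list alone), heat shock proteins (0.184; 1 higher) or SRF and YAP targets (0.146; 3 higher). The same held for thyroid hormone handling (0.683; 1 lower when adjusted over the list alone), blood cell markers (0.904; 1 higher) and smooth muscle and pericyte markers (0.524; 1 higher). In these lists NUPR1 differed by a log2 change of 0.84, CRYAB by 1.25 (adjusted p = 0.0911), ACTA2 by 0.64, DIO2 by -0.32 and CD14 by 0.53 (adjusted p = 0.0978). None of 4 epithelial cell markers, too few for camera, passed by either adjustment (CLDN7 differed by -0.16). The median and the mean differed in sign for matrix proteases and inhibitors (0.00 to 2 decimals and 0.04), oxidative phosphorylation (0.02 and -0.01), and blood cell markers (-0.06 and 0.03).

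The 3 Omnipaque arrays lay outside the range of the 3 control arrays for 31.34% of genes, where chance gives 10%, and 2142 genes had an unadjusted p below 0.05. The count of 145 became 27, 22 and 28 without control replicates 1, 2 and 3, and 35, 39 and 86 without Omnipaque replicates 1, 2 and 3. It became 95 and 96 without Isovue replicates 1 and 2, and 2114 without Isovue replicate 3, all 145 genes included. No Isovue array enters this difference, so the counts without an Isovue replicate moved through the shared estimate of spread. With the replicate number as a block the count was 82. Of 31 named changed genes, 12 passed in each of the 9 fits that left out 1 array, among them HMGCS1, SQLE, ISG20, OAS3, S100A4 and VWF, as did 9 of 10 called lists. Without Isovue replicate 3 no list held with an estimated correlation in any comparison (smallest adjusted p = 0.0856). In simulated data for this comparison, 78% of genes with a log2 change of 1 and 96% with a change of 2 were recovered, and 5 of 162 called genes were false.

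After 24 h with Isovue, interferon response genes, metallothioneins and most changed genes of NF-kB and inflammatory secretion fell, and genes of cholesterol synthesis rose. IFI44L, an interferon-induced gene, fell by 2.98 on the log2 scale (SE 0.3, adjusted p = 0.00131), from 11.64 ± 0.0721 to 8.66 ± 0.486 (SD, n = 3 arrays each). AKR1C4 rose by a log2 change of 2.24 (SE 0.115, adjusted p = 4.541e-05). AKR1B1, aldose reductase, which makes the osmolyte sorbitol, rose by a log2 change of 2.00 (SE 0.143, adjusted p = 0.000177). Of 19280 genes, 852 passed the threshold in limma (4.42%), 433 higher and 419 lower, and 177 of them changed at least 2-fold, 94 upward and 83 downward.

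Of 20 tested interferon response genes, 16 fell after Isovue and none rose (18 fell when adjusted over the list alone). The median log2 change was -1.51 (camera adjusted p = 6.426e-25, and adjusted p = 0.0114 with an estimated correlation). IFI44, OAS3 and OAS2 fell by log2 changes of -2.37, -2.21 and -2.19. MX2, EPSTI1 and USP18, which restrains interferon signalling, fell by log2 changes of -2.80, -2.38 and -2.07. The list means were below the control mean on all 3 Isovue arrays, at -1.38, -1.37 and -1.48. Of 8 metallothioneins and zinc transport genes, 6 fell (6 when adjusted over the list alone), among them MT1X (-1.42), MT1E (-1.36) and MT1G (-1.11). The metallothionein list had a median of -0.63 (camera adjusted p = 3.629e-09, and adjusted p = 0.0124 with an estimated correlation). Of 24 genes of NF-kB and inflammatory secretion, 10 fell and 1 rose (14 fell and 1 rose when adjusted over the list alone). IL8 (now CXCL8), CXCL2 (detected on 2 of 3 Isovue arrays) and CXCL6, chemokines that attract neutrophils, fell by log2 changes of -2.17, -1.47 and -1.27. CCL2, which attracts monocytes, was the member that rose, by 0.61 (named after its values were seen). The list's median was -0.43 (camera adjusted p = 1.235e-07, and adjusted p = 0.0173 with an estimated correlation).

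Of 23 cholesterol synthesis genes, 18 rose after Isovue and none fell (21 rose when adjusted over the list alone). The median log2 change was 1.37 (camera adjusted p = 9.989e-26, and adjusted p = 0.0224 with an estimated correlation). MVD, which makes isopentenyl diphosphate, rose by a log2 change of 2.50, DHCR7 by 2.13 and ACAT2 by 2.03. TM7SF2, a sterol reductase outside the list, rose by a log2 change of 2.68. Without Isovue replicate 3 the log2 change was 1.86 for MVD and 1.97 for TM7SF2, and both calls ended without any 1 of the 3 control arrays or Omnipaque replicate 1 or 2. Of 25 lysosome and autophagy genes, 4 rose (10 higher and 1 lower when adjusted over the list alone), among them MCOLN1 (1.33), NPC1 (0.94) and GLA (0.54). The lysosome list had a median of 0.46 (camera adjusted p = 7.018e-06, and adjusted p = 0.0349 with an estimated correlation). Of 23 NRF2 and antioxidant genes, AKR1C3 (log2 change 2.22), ME1 (1.25) and AKR1C2 (0.79) rose (10 higher and 2 lower when adjusted over the list alone). The NRF2 list had a median of 0.33 and a camera adjusted p of 0.000552, which became adjusted p = 0.232 with an estimated correlation.

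Of 16 hypertonic response genes, 5 rose after Isovue (5 when adjusted over the list alone), among them AKR1B1 (2.00), SLC5A3 (1.82) and S100A4 (1.64). The hypertonic list had a median of 0.02 and a camera adjusted p of 0.0245, which became adjusted p = 0.145 with an estimated correlation. That call ended without Isovue replicate 1 (0.118) or 2 (0.144), and the list means were 0.43, 0.44 and 0.02 on Isovue replicates 1, 2 and 3. ISYNA1, which makes myo-inositol, rose by a log2 change of 2.56, and CRYAB, a small heat shock protein, by 2.48 (SE 0.27, adjusted p = 0.002). FABP3, a fatty acid carrier, was at least 4.39-fold higher and not detected on any control array. PRSS35 rose by a log2 change of 2.83 (3.53 without Isovue replicate 3), HSD17B14, a steroid dehydrogenase, by 2.55, TMEM119, a membrane protein of bone cells, by 2.35 and VWF by 1.30. RGS4, which shortens G protein signalling, fell by a log2 change of -2.27. Isovue replicate 3 lay furthest from control for ISYNA1 (11.80, against 10.046 and 10.155 on replicates 1 and 2) and HSD17B14 (10.03, against 8.46 and 8.40). The same held for TMEM119 (10.71, against 9.09 and 9.06), FABP3 (9.10, against 7.865 and 7.918) and RGS4 (8.16, against 9.242 and 9.425). Each of these calls ended without any 1 of the 3 control arrays. CRYAB also lay highest on replicate 3 (10.51, against 9.62 and 9.735).

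Of 35 tested cell cycle and proliferation genes, MKI67 (log2 change -1.19), MCM3 (-0.80) and CCNE2 (-0.45, detected on 2 of 3 Isovue arrays) fell after Isovue over all genes, and 26 fell when adjusted over the list alone. The list's median was -1.13 and its camera adjusted p 8.051e-13, which became adjusted p = 0.376 with an estimated correlation. The cell cycle list means on Isovue replicates 1, 2 and 3 were -0.75, -0.74 and -1.80. Of 17 immediate early genes, FOSL1 fell by a log2 change of -1.02 (1 fell when adjusted over the list alone). The immediate early list had a median of -0.42 and a camera adjusted p of 0.00313, which became adjusted p = 0.476 with an estimated correlation. The call ended without Isovue replicate 3 (camera adjusted p = 0.0888), where the median was -0.13. The immediate early list means on Isovue replicates 1, 2 and 3 were -0.04, -0.36 and -1.04.

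Camera made no call after Isovue for the other 17 tested lists. In the unfolded protein response, 1 of 19 genes rose and 4 fell (2 higher and 5 lower when adjusted over the list alone; camera adjusted p = 0.0526), among them HSPA5, the chaperone BiP (-0.88), SDF2L1 (-0.73) and CRELD2 (-0.54). In hypoxia and glycolysis, 4 of 23 genes rose and 1 fell (4 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.124), among them ALDOC (1.94), PFKFB4 (0.92) and PFKFB3 (0.73). Without Isovue replicate 3 that list's camera adjusted p was 0.00595, which became adjusted p = 0.158 with an estimated correlation. ALDOC lay furthest from control on Isovue replicate 3 (11.84, against 10.43 and 10.35 on replicates 1 and 2). TRIB3 (0.78) rose in ATF4 and integrated stress response (camera adjusted p = 0.715; 3 higher and 2 lower when adjusted over the list alone), where the median of -0.14 and the mean of 0.04 differed in sign. TNFRSF10B (0.41), a death receptor, and CDKN1A (0.36), the cell cycle inhibitor p21, rose among p53 targets (camera adjusted p = 0.093; 3 higher when adjusted over the list alone). CRYAB was the 1 heat shock protein to rise (camera adjusted p = 0.124; 1 when adjusted over the list alone). Among matrix proteases and inhibitors, 3 rose and 1 fell (camera adjusted p = 0.829; 3 higher and 2 lower when adjusted over the list alone), with PLAT at 1.14 and TIMP2 at 0.48 among those that rose. Among mesenchymal stromal surface markers PDGFRB (1.28) and CD9 (0.86) rose and NT5E (-0.88), the marker CD73, fell (camera adjusted p = 0.166; 3 higher and 1 lower when adjusted over the list alone).

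Among osteogenic, adipogenic and chondrogenic genes SPP1 rose by a log2 change of 0.53 after Isovue and MSX2 fell by -0.49 (camera adjusted p = 0.765; 1 higher and 1 lower when adjusted over the list alone). TNS1 (0.58) rose among SRF and YAP targets (camera adjusted p = 0.953; 1 higher and 1 lower when adjusted over the list alone). DIO2 (-0.38, detected on 1 of 3 Isovue arrays), which activates thyroid hormone, fell in thyroid hormone handling (camera adjusted p = 0.904), VWF rose among endothelial cell markers (0.409) and CD14 (1.10), a monocyte marker, among blood cell markers (0.324), each as the 1 member past the threshold, also when adjusted over the list alone. No member passed over all genes in apoptosis machinery (camera adjusted p = 0.164; 2 lower when adjusted over the list alone). None passed by either adjustment in extracellular matrix (0.705), oxidative phosphorylation (0.517), smooth muscle and pericyte markers (0.701) or ribosomal proteins (0.104), where the ribosomal camera adjusted p was 0.00595 without Isovue replicate 3, which became adjusted p = 0.574 with an estimated correlation. The largest differences in these lists were BAK1 (-0.51, adjusted p = 0.061), TNC (1.25, adjusted p = 0.0729), UQCRC2 (-0.57), CSPG4 (-0.46) and RPL7 (-0.78). Isovue replicate 3 lay furthest for TNC (10.30, against 9.15 and 9.17 on replicates 1 and 2) and for RPL7 (8.62, against 9.89 and 10.13). Of 4 epithelial cell markers none passed by either adjustment, and EPCAM, detected on 2 control and 2 Isovue arrays, differed by 0.06. The median and the mean differed in sign for extracellular matrix (-0.02 and 0.04) and matrix proteases and inhibitors (-0.13 and 0.02).

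The 3 Isovue arrays lay outside the range of the control arrays for 31.48% of genes, where chance gives 10%, and 4155 genes had an unadjusted p below 0.05. The count of 852 became 227, 206 and 185 without control replicates 1, 2 and 3, 452 and 445 without Omnipaque replicates 1 and 2, 458 and 511 without Isovue replicates 1 and 2, and 2839 without Isovue replicate 3, all 852 genes included. Of 57 named changed genes, 25 passed in each of the 9 fits that left out 1 array, among them AKR1B1, CRYAB, IFI44L, OAS3, IL8 and MT1X, as did 7 of 9 called lists. In simulated data with the wide spread of the Isovue arrays, 78% of genes with a log2 change of 1 and 98% with a change of 2 were recovered, and 162 of 324 called genes were false. That simulation gave all 3 Isovue arrays the same wide spread, whereas in the data replicate 3 alone stood apart, so its shares may not hold for the data.

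**Figure D1:**
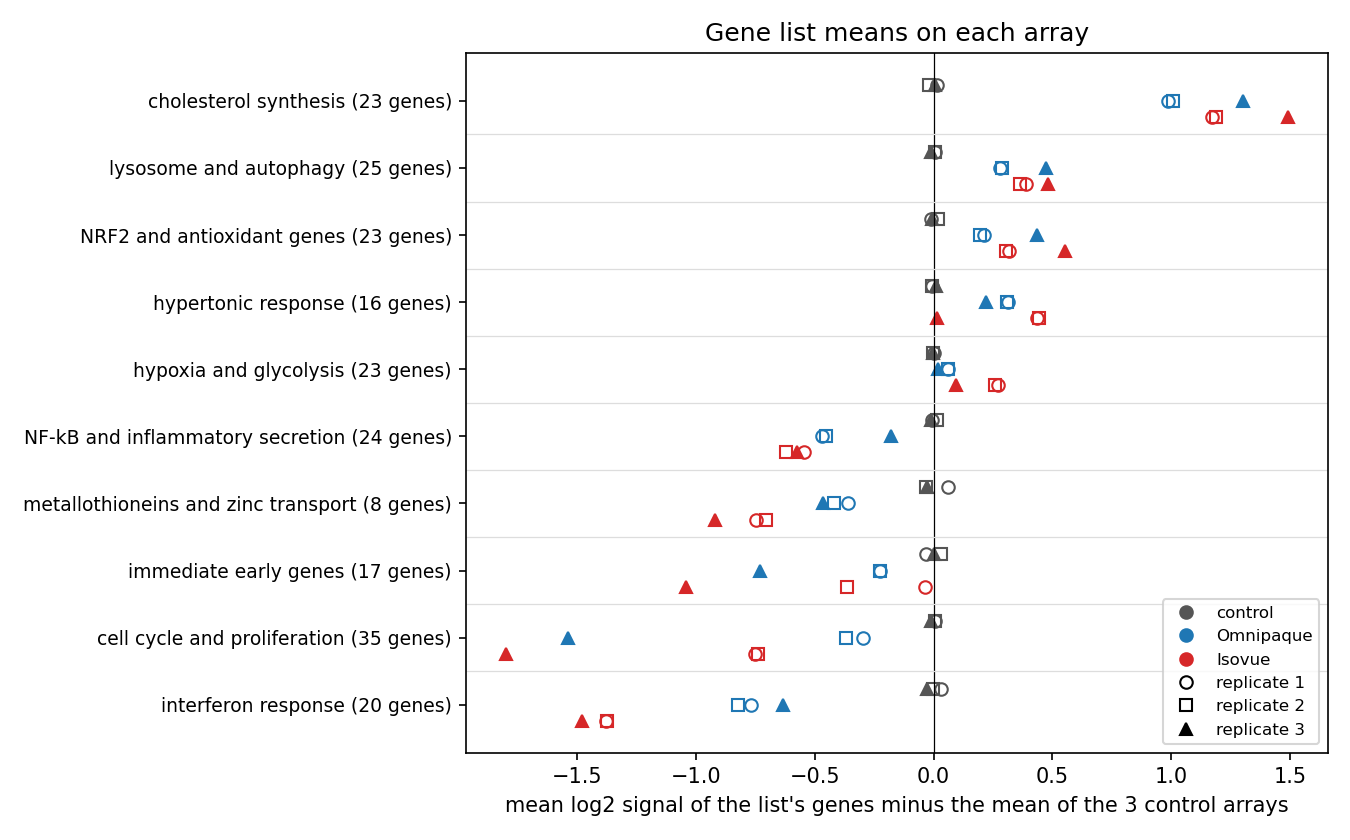
Each point is the mean log2 signal of a gene list on 1 array minus the mean of the 3 control arrays (x axis), for 10 lists (y axis), coloured by group with a shape per replicate. Interferon response means lay between -1.48 and -1.37 after Isovue and between -0.82 and -0.63 after Omnipaque, and the cell cycle means of both replicates numbered 3 lay lowest.

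The agents could be compared directly at the same dilution by volume and the same time, though not at a known iodine dose. Iohexol and iopamidol are both nonionic monomers with a triiodinated benzene ring and differ in their side chains. Iohexol has an N-acetyl dihydroxypropylamino group and dihydroxypropyl amides, and iopamidol has a lactic acid amide and amides of serinol. Interferon response genes and metallothioneins were lower after Isovue than after Omnipaque, and AKR1C4 and AKR1B1 were higher. Of 19280 genes, 12 differed in limma, 4 higher and 8 lower after Isovue, and 6 of them by at least 2-fold.

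AKR1C4 was higher after Isovue by a log2 difference of 1.29 (95% interval 1.02 to 1.55, adjusted p = 0.0125), and AKR1B1 by 1.25 (0.93 to 1.58, adjusted p = 0.0216). FZD9, a Wnt receptor, and ENO3, a glycolytic enolase, were higher by 0.99 (0.81 to 1.17) and 0.65 (0.49 to 0.82). USP18 was lower after Isovue, with a log2 difference of -1.19 (95% interval -1.47 to -0.92, adjusted p = 0.0148). OAS2, MX1 and OAS3, antiviral genes induced by interferon, had log2 differences of -1.13, -1.09 and -1.06. MT1E differed by -0.87, MT1X by -0.84 (95% interval -1.02 to -0.66), C20ORF127, now the metallothionein pseudogene MT1P3, by -0.87 and HES4 by -0.83. All 3 Isovue arrays lay on one side of all 3 Omnipaque arrays for each of these 12 genes.

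Of 20 interferon response genes, 3 were lower after Isovue than after Omnipaque (13 when adjusted over the list alone), with a median log2 difference of -0.67 (camera adjusted p = 7.782e-17, and adjusted p = 0.0124 with an estimated correlation). Of 8 metallothioneins and zinc transport genes, MT1E and MT1X were lower (3 when adjusted over the list alone), with a median of -0.29 (camera adjusted p = 1.704e-05, and adjusted p = 0.0224 with an estimated correlation). No member passed over all genes in the other lists that camera called. NF-kB and inflammatory secretion had a median of -0.20 (1 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.00301), which became adjusted p = 0.0966 with an estimated correlation. Cell cycle and proliferation had a median of -0.34 (none when adjusted over the list alone, camera adjusted p = 0.00058), which became adjusted p = 0.647 with an estimated correlation. Its median was -0.06 without Isovue replicate 3. Hypoxia and glycolysis had a median of 0.21 (none when adjusted over the list alone, camera adjusted p = 0.0334), which became adjusted p = 0.145 with an estimated correlation. Cholesterol synthesis had a median of 0.15 (none when adjusted over the list alone, camera adjusted p = 0.0127), which became adjusted p = 0.476 with an estimated correlation.

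The calls of 4 of these 6 lists ended when 1 array was left out. The cell cycle list lost its call without Omnipaque replicate 1 (camera adjusted p = 0.157), Omnipaque replicate 2 (0.088) or Isovue replicate 3 (0.48), and the NF-kB list without Omnipaque replicate 3 (0.0751) or Isovue replicate 2 (0.0694). The cholesterol list lost its call without Omnipaque replicate 1 (0.0944) or 2 (0.108), and the hypoxia list without Omnipaque replicate 3 (0.0985) or Isovue replicate 1 (0.222) or 2 (0.162). Without Isovue replicate 3 camera called the hypertonic (adjusted p = 0.0242), p53 targets (0.00305), ATF4 (0.00578) and smooth muscle and pericyte (0.0234) lists, which became adjusted p = 0.257, 0.127, 0.581 and 0.198 with an estimated correlation. The other 20 tested lists had camera adjusted p-values from 0.0958 for SRF and YAP targets to 0.993 for osteogenic, adipogenic and chondrogenic genes.

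For several genes that were higher after both agents, no difference between them was detected. The log2 difference was 0.00 for HMGCS1 (95% interval -0.29 to 0.30), -0.03 for VWF (-0.34 to 0.27) and 0.19 for SC5DL (-0.10 to 0.47). For FABP3, called after Isovue and not after Omnipaque (adjusted p = 0.1), it was 0.33 with a wide interval of -0.66 to 1.32. CRYAB, also called after Isovue alone, differed between the agents by 1.23 (0.62 to 1.84) without passing the test (adjusted p = 0.33). HMGCS1, VWF, SC5DL and FABP3 were chosen for this comparison after their values were seen.

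The Isovue and Omnipaque arrays did not overlap for 15.93% of genes, where chance gives 10%, and 1538 genes had an unadjusted p below 0.05. The count of 12 became 0 without control replicate 2 or 3, without Omnipaque replicate 1 or 2 and without Isovue replicate 1, and became 72 without Isovue replicate 3, all 12 genes included. With the replicate number as a block it became 0. None of the 12 genes passed in all 9 of these fits. In simulated data for this comparison, 78% of genes with a log2 difference of 1 were recovered, and 158 of 312 called genes were false. The simulation gave all 3 Isovue arrays the same wide spread, whereas in the data replicate 3 alone stood apart. It called 312 genes where the data gave 12, so its shares do not carry over to the data.

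**Figure D2:**
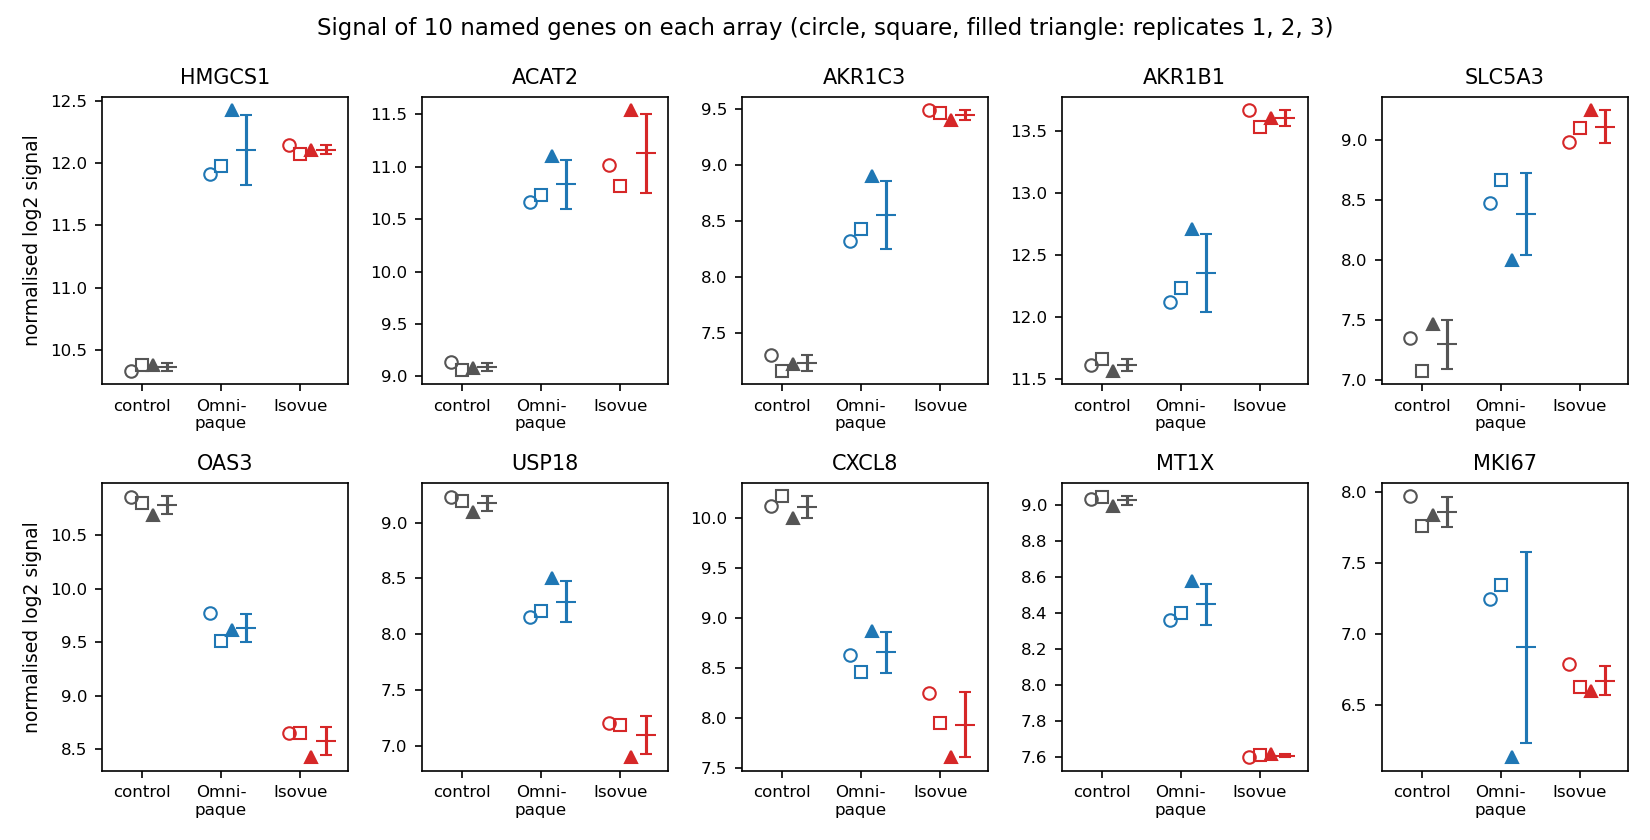
Each panel shows the normalised log2 signal (y axis) of 1 gene on the 9 arrays by group (x axis), with a shape per replicate, and beside them the mean and SD of the 3 arrays. HMGCS1 rose to 12.11 after Omnipaque and AKR1B1 to 13.61 after Isovue, and MKI67 was lowest on Omnipaque replicate 3.

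The fold changes of both agents against control went largely together across genes. Pearson's r was 0.7 and Spearman's rho 0.56, where genes are not independent replicates. Groups simulated without change against shared controls gave a mean r of 0.21 and a maximum of 0.231 over 100 simulations. These simulations gave all 3 Isovue arrays the wide spread that replicate 3 brings, which lowers the simulated r. The simulations drew all arrays independently and so leave out the correlation of the Omnipaque and Isovue arrays of the same number (0.363, 0.128 and 0.35 in group-centred values). Omnipaque 1 with Isovue 2 (0.359) and Omnipaque 2 with Isovue 1 (0.149) correlated alike. Each array numbered 3 correlated negatively with replicates 1 and 2 of the other dye (-0.382 to -0.146). Centred values of the 3 arrays of a group sum to 0, so these correlations depend on each other and are not separate observations. The covariance was 0.0539 against 0.00511 in the simulations, and the share of genes with the same sign 69.18% against 60.42%. Of the 82 genes that rose after Omnipaque, 73 also rose after Isovue. Of the 63 genes that fell, 60 also fell, and no gene was called in opposite directions. Of the 145 Omnipaque genes, 109 (75.17%) had the larger change after Isovue, but of the 1408 genes called for Omnipaque without any Isovue array in the fit, 50.64% did. Both sets were picked for their change after Omnipaque, which lowers such shares, so neither share compares the 2 responses in size. The correlation was 0.865 without Isovue replicate 3, 0.575 without Omnipaque replicate 3, and 0.594 and 0.588 without Isovue replicates 1 and 2. No simulated values without an array were set beside these. The same 3 control arrays serve both comparisons, and the simulations cover their spread but not a condition common to all 3, such as their medium, for which no matching dilution is given.

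**Figure D3:**
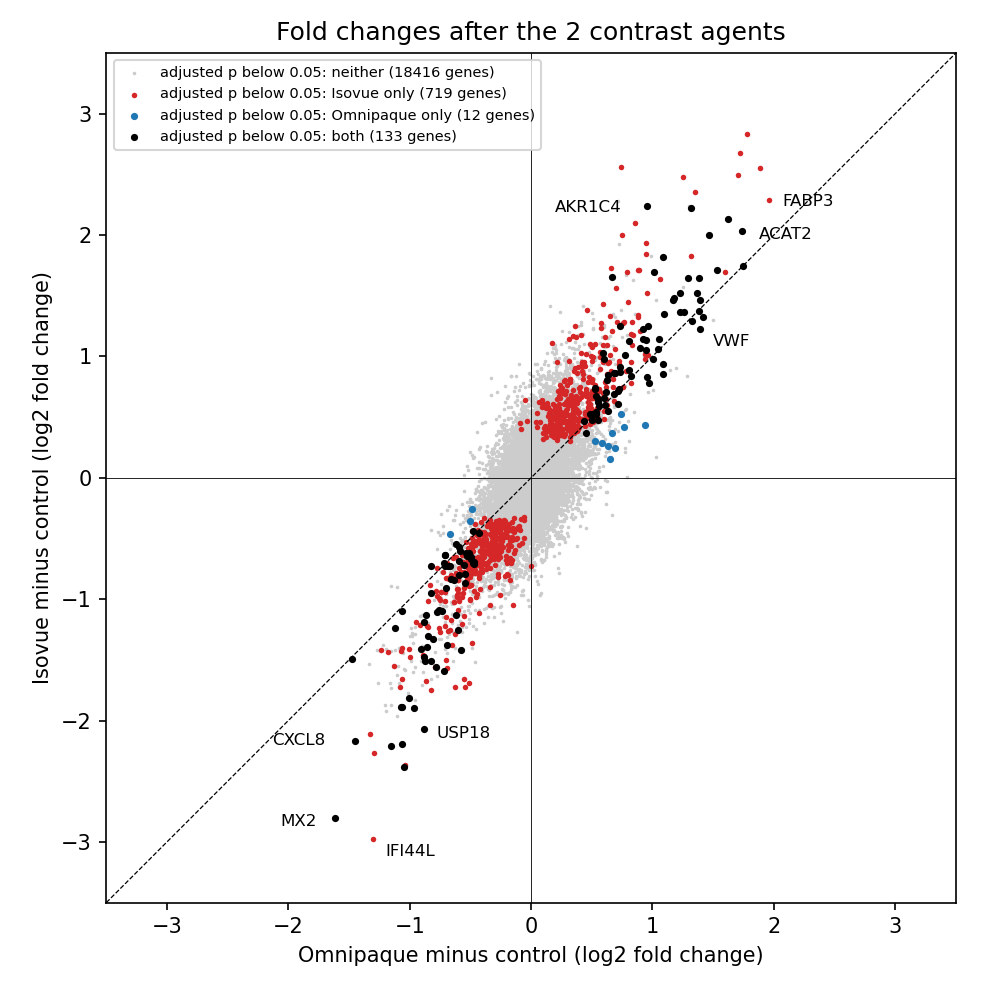
Each point is 1 of 19280 genes, with its log2 fold change after Omnipaque (x axis) and after Isovue (y axis), coloured by which comparisons passed the threshold, and the dashed line marks equal changes. ACAT2 and AKR1C4 lie at the upper right and MX2 and CXCL8 at the lower left, as 2 of the 73 genes that rose and 2 of the 60 that fell after both agents.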

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

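The direct test between the agents, the replicate block, the estimated correlation and the counts of splits were chosen before the data were examined. The test of a stronger response on Isovue replicate 3 is recorded as set beforehand, but it concerns an array that had to be seen to stand apart. The other tests in this part were chosen after the result was seen.

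The agents differed in 12 genes and 6 gene lists by the direct test between them, but 0 genes remained with the replicate number as a block, and 2 lists, interferon response and metallothioneins, with an estimated correlation. The log2 differences, Isovue minus Omnipaque, were 1.29 for AKR1C4, 1.25 for AKR1B1, 0.99 for FZD9 and 0.65 for ENO3. They were -1.19 for USP18, -1.13 for OAS2, -1.09 for MX1, -1.06 for OAS3, -0.87 for MT1E, -0.87 for C20ORF127, -0.84 for MT1X and -0.83 for HES4. The medians of the lists were -0.67 for interferon response, -0.34 for cell cycle and proliferation, -0.29 for metallothioneins, -0.20 for NF-kB and inflammatory secretion, 0.21 for hypoxia and glycolysis and 0.15 for cholesterol synthesis. Without Isovue replicate 3 they were -0.64, -0.06, -0.23, -0.25, 0.14 and 0.10 in the same order.

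Isovue replicate 3 differed at least 2-fold from the mean of Isovue replicates 1 and 2 in 1912 genes, where those replicates differed from each other in 2. A wrong label on an array of another group is argued against, since of 72 genes called between the agents without this array, 55 (76.4%) lay on it nearest to the mean of Isovue replicates 1 and 2, 15 nearest to Omnipaque and 2 nearest to control. A sample from outside the series stays open. A stronger response over all responding genes is argued against as well. Of the 1408 genes called for Omnipaque without any Isovue array, 41.9% lay further in that direction on this array than on the mean of Isovue replicates 1 and 2. Those 2 replicates were each compared with the other alone (53.48% and 46.31%). Their shares mirror each other and are no benchmark for the 41.9%. Some lists did lie further on Isovue replicate 3 than on Isovue replicates 1 and 2. The means were 1.49 against 1.17 and 1.19 for cholesterol synthesis, 0.55 against 0.32 and 0.30 for NRF2 and antioxidant genes, and -1.80 against -0.75 and -0.74 for cell cycle. A stronger response of these lists stays open. A loss of short-lived transcripts cannot be told apart, since the median of the immediate early genes lay at percentile 0.05 of matched random lists, but that of the NF-kB list, which also holds short-lived transcripts, at percentile 65.9, and that of the cell cycle list at 0. Slower division or a change in RNA handling before labelling could not be separated by these arrays.

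Interferon response genes were lower after both agents. A loss of blood cells from treated cultures is argued against, though by few markers. Of 14 blood cell markers, 5 were detected on all control arrays (CD14, CD79A, HLA-DRA, CD74 and HBB), and PTPRC, LYZ and TYROBP on no array. The median log2 change of those 5 lay between -0.13 and 0.14 on the treated arrays. Had their signal above the undetected genes fallen by the same factor as the interferon list, it would lie between -0.54 and -0.27. CD14 differed by 0.53 after Omnipaque and rose by 1.10 after Isovue. CD79A, HLA-DRA, CD74 and HBB differed by -0.124, -0.069, -0.032 and -0.055 after Omnipaque and by 0.082, -0.115, 0.479 and -0.234 after Isovue. CD79A and HBB lay only 0.32 and 0.50 on the log2 scale above the undetected genes in the controls. CD79A was detected on no Omnipaque array and on all 3 Isovue arrays. Quantile normalization leaves little room for a shift of all genes of like brightness. That 0 of 10000 random lists matched on brightness had a median as low in either comparison therefore adds little. A lower interferon signal in cells exposed to either dye is therefore a hypothesis that these tests leave open, and a difference in culture conditions between control and treated flasks may give the same pattern and was not tested.

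Interferon response genes changed more after Isovue than after Omnipaque, while over the 1408 genes called for Omnipaque without any Isovue array the share with the larger change after Isovue was 50.64%. These genes were picked for their change after Omnipaque, which by itself lowers the share with the larger change after Isovue. Their shares thus cannot decide whether Isovue replicate 3 is the only source of larger changes. Without that replicate the share was 58.1%, and with only replicates 1 and 2 of each dye it was 66.26%. Isovue replicate 3 taken by itself gave the lowest share of the 3 arrays (45.31%, against 59.09% and 58.24%). For the interferon list, the higher mean of Isovue replicates 1 and 2 was -1.37, below the lowest Omnipaque array at -0.82. This argues against Isovue replicate 3 as the only source for that list. A single factor between the agents for all genes is argued against, since the lowest ratio of Isovue to Omnipaque over pairs of arrays was 1.67 for the interferon list and the highest was 1.51 for the cholesterol list. A different iodine dose in the same volume of dye may still act unequally on these lists and was not tested.

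With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For Omnipaque against control, the real split alone (1 of 10) gave 145 genes, and the highest other gave 0. For Isovue against control, it alone (1 of 10) gave 852 genes, and the highest other gave 0. For Isovue against Omnipaque, it alone (1 of 10) gave 12 genes, and the highest other gave 0. The lists called were 10 against 9 for the highest other split in the first comparison, 9 against 5 in the second and 6 against 5 in the third, again with 1 of 10 splits as high. Splits that mixed the groups thus also gave list calls by camera with its preset correlation. Such a split keeps part of the difference between the groups and adds the rest to the spread. Its counts of genes and lists are therefore no measure of what chance gives.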

How the results depend on the processing

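The background correction and detection limit of the analysis given, the background from the signal mode, the looser detection limit and leaving out both arrays numbered 3 were chosen after the result was seen, and the other alternatives before the data were examined. The Omnipaque count of 145 became 38 at 2-fold, 31 against a fold of 1.2, 78 with the mode as background, 1408 with only the 2 groups compared, 82 with a replicate block, 89 with trend and robust moderation, 3300 with array weights and 2546 without both arrays numbered 3. The Isovue count of 852 became 177, 153, 453, 5718 and 4678 at 2-fold, against a fold of 1.2, with 2 groups, with weights and without both arrays. The count of 12 between the agents became 6 at 2-fold, 0 against a fold of 1.2, 6 with the mode, 0 with 2 groups and 0 with the block (1538 unadjusted in the limma fit of all arrays), 1230 with weights and 668 without both arrays. Leaving out 1 array gave 22 to 2114, 185 to 2839 and 0 to 72 genes. The correlation of 0.7 between the agents was 0.829 with weights, 0.807 without both arrays and 0.575 to 0.865 without 1 array. With an estimated correlation 5, 5 and 2 lists remained of 10, 9 and 6 called by camera, and 10 were called between the agents without both arrays. Without 1 array 9 to 10, 8 to 10 and 4 to 9 lists were called, and with the replicate block 9, 8 and 6. Array weights were 0.0495 for Isovue replicate 3 and 0.377 for Omnipaque replicate 3. Stricter thresholds lower a count by construction. No Isovue array enters the difference of Omnipaque and control. Leaving out Isovue replicate 3 (2114 genes) or comparing the 2 groups alone (1408) thus moved that count through the estimate of spread. Without that replicate the counts were 2114 for Omnipaque and 2839 for Isovue, so 145 and 852 do not compare the sizes of the 2 responses. For the other changes the cause was not tested.

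Median scaling gave 149, 849 and 12 genes, cyclic loess 169, 847 and 16, and no background correction 189, 950 and 14, within 1.5 times the counts given. The deposited signals were already quantile-normalized, so median scaling and cyclic loess could move the counts little and do not test that step. With the replicate block, 22 of 121 named gene results lost the call and 2 gained it. Over 2533 values of these results under alternatives, 2052 kept direction and side of the threshold, 419 lost the call, 61 gained it and 1 reversed. The reversed value was EPCAM after Isovue, not called at 0.06, which was -0.0125 without control replicate 2 and ranged from -0.0125 to 0.104 without 1 array. Of 575 list values 530 kept the call and 45 lost it. The mean of a gene's probes and a chip block were not run, since probe names and chips are not given. The background (neqc) and filter by detection p-values served only in a first analysis whose results are not reported, and were not run as alternatives to the analysis given. Detection, at a log2 signal of 6.92, limits what can be seen to about 51.73% or less of the genes on an array.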

Other observations

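All values in this part were chosen after the result was seen. The genes named here were picked from those that differed most on Isovue replicate 3. Against the mean of Isovue replicates 1 and 2, the log2 signal of ECT2, needed for cytokinesis, differed by -2.87, TOP2A by -2.80, CDKN3 by -2.62 and ANLN by -2.34. The immediate early genes EGR1 and FOS differed by -3.43 and -3.05. RARRES2 and DMPK lay above, by 3.02 and 2.55. Of 19280 genes, 931 were at least 2-fold higher and 981 at least 2-fold lower on this array. Omnipaque replicate 3 differed in 122 genes from the mean of its own replicates 1 and 2, and the deviations of both arrays correlated with r = 0.35 across genes. The median difference on Isovue replicate 3 was -0.94 for cell cycle genes and -0.74 for immediate early genes.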
